A study of Leishmania amazonensis with 3 samples.

How the data were processed

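Total RNA of Leishmania amazonensis promastigotes, the flagellated insect-stage form of this protozoan parasite, was profiled by RibOxi-seq in 3 libraries. Per the labels' protocols, the parasites were grown in M199 medium with 10% serum at 27 °C, and 1 µg of total RNA entered each library. RibOxi-seq maps ribose 2'-O-methylation (Nm). RNA is fragmented, here with the nuclease Benzonase, and rounds of oxidation, β-elimination and dephosphorylation then act on the 3' ends. A methyl group on the 2' oxygen protects the last ribose from oxidation, so that fragments ending at a methylated nucleotide are retained for adapter ligation. A pile-up of fragment ends at 1 position over its surroundings is therefore the measurement of interest.

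The deposited count table gives raw counts, not normalized, for each position of 8 rRNA sequences in each library. Some positions have no row. They were taken as having no count in any library, although a filter that is not described could also have removed them. The submitters' processing notes name cutadapt 2.10, STAR 2.7.5c, SAMtools, UMI-tools 1.01 and bedtools 2.29.2, without their settings or order. UMI-tools handles molecular identifiers, but whether the deposited counts are deduplicated molecules is not given in the sources used here. The reference sequences, the genome build, the strand and the filters are also not given in the sources used here. Positions are therefore reported by the rRNA name and the number in the files, without the nucleotide or a genomic location. Which nucleotide of a fragment end was numbered (the end itself or its neighbour) is likewise not given. The first listed position is 20 in 7 rRNAs and 21 in SSU.

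The deposited score table gives 1 ratio per position, the authors' mean over the 3 libraries, for the SSU, LSU5, LSU3 and 5.8S sequences. The formula was worked out from the counts: in each library, the count at the position was divided by the mean of the counts in the row before and the row after, plus 1, and the 3 ratios were averaged. This gave the deposited ratio at 5577 of 5577 positions within a relative tolerance of 1e-06. At the ends of a sequence only the 1 existing neighbour entered. Because the neighbour was the adjacent row, a position without a row was skipped and not taken as 0. The same formula was used here to obtain the score per library, its SD, and scores for the SR1, SR2, SR4 and SR6 sequences.

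All 3 libraries form 1 group. The design holds no untreated, unoxidised or second condition, so each position was compared with its surroundings in the same library. For every position from the first to the last listed one (absent rows taken as 0), the count was compared with the summed counts of the 6 positions on each side. The model was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3), with the library as a block, the library total as the library size and an offset for the number of flank positions. A position was tested if at least 6 flank positions existed and position plus flank held at least 10 counts over the 3 libraries. It was called enriched at a Benjamini-Hochberg adjusted p under 0.05 and an estimated fold of 4 or more over the flank mean. The fold printed with an SD is the mean over libraries of count over flank mean. No TMM or other factor was estimated between position and flank. Neighbouring tests share flank counts and are not independent. Fisher's exact tests compared the density of enriched positions between rRNAs (SciPy 1.17.1 in Python 3.11.15).

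The positions named were fixed by a rule set before the data were examined. They are the 25 enriched positions with the largest estimated fold that were local maxima within 2 positions and at least 4-fold over the flank in each library, the 10 positions with the highest deposited score, and the most enriched position of each rRNA. These make 33 positions. Others are marked as chosen after their values were seen. Planned tests of the nucleotide at enriched positions, and the values at 3 conserved sequence landmarks, were not run because no rRNA sequence was used here.

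Library totals ranged from 212914 to 229882 counts, and the median position held 16 to 20 counts per library, so that single background positions carry a large counting error while the strongest enriched positions do not. The common biological coefficient of variation of the model was 8.25%. The test was checked on counts simulated at the real positions, with a smooth background. Of 66 positions simulated 32-fold over background all were called, and of 67 at 8-fold 56 were called (83.6%). Of 67 at 2-fold 0 were called, and of 5930 unchanged positions 0 were called. By the adjusted p alone, 68.7% of the 2-fold and 2.75% of the unchanged positions passed as higher than their flank. The fold threshold kept these out, so the 0 calls do not measure the error rate of the adjusted p. The real background is not smooth, and the simulation does not cover this.

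Alternatives were the flank size, a flank without the nearest positions, the flank median with limma 3.58.1, DESeq2 1.42.0, TMM and median-of-ratios factors between position and flank (run without the offset for the number of flank positions, which raises the fold where the flank is short), filters on low counts, fold thresholds of 2 and 8, no library block, sequence ends left out, local maxima only, and each library left out in turn. Alternatives chosen after seeing the data were flanks without the enriched positions, a test against a fold of 4, a flank on the 5' side only, the same TMM and median-of-ratios factors with the offset kept, and the correlation between libraries without the enriched positions.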

Results

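Fragment ends in the rRNA of Leishmania amazonensis promastigotes were counted in 3 RibOxi-seq libraries to map 2'-O-methylated nucleotides. The count table covered 8 rRNA sequences, under the names used in the files: SSU, the RNA of the small ribosomal subunit, LSU5 and LSU3, 5.8S, SR1, SR2, SR4 and SR6. In kinetoplastids the RNA of the large subunit is made as several separate pieces. The total counts were 229882, 212914 and 214074 in libraries 1, 2 and 3. SSU took 35.1% ± 0.244 (SD, n = 3) of the counts, LSU5 29.5% ± 0.562, LSU3 24.2% ± 0.272, 5.8S 3.14% ± 0.0947 and SR1 3.10% ± 0.119. The remaining counts lay in SR2, SR4 and SR6. Of the positions between the first and the last listed, 6106 had a row, and 24 had no row and were taken as 0 counts. The labels give the libraries strain designations that differ only in the final number and do not say whether they came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

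The 3 libraries gave closely similar profiles along the rRNA. Across 5645 positions with at least 10 counts in total, Pearson's r of log2(count + 1) was 0.92 between libraries 1 and 2, 0.92 between libraries 1 and 3 and 0.93 between libraries 2 and 3. Positions within a library are not independent replicates, and r is given as a description. The counts differed by more than sampling noise in each pair, with chi-square values of 1.36, 1.78 and 1.19 per degree of freedom over 5644 degrees of freedom. Whether duplicate reads were removed is not given in the sources used here, and duplicates would also raise this ratio. Over the enriched positions described next, where counts are higher, the same ratios were 2.73, 4.14 and 1.95.

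Fragment ends were concentrated at a small number of positions. Of 6127 positions tested, 214 were enriched at an estimated fold of 4 or more over their flank (edgeR's quasi-likelihood test, largest adjusted p = 0.00739). Among them 99 were at least 8-fold and 58 at least 16-fold. The p tests for any difference from the flank, and not for a fold of 4. These 214 positions, 3.49% of all, held 28.1% ± 1.61 (SD, n = 3) of the counts, and the 58 strongest held 15.3% ± 1.00. In the individual libraries the share at enriched positions was 26.5%, 28.2% and 29.7%. Every one of the 3 libraries exceeded 4-fold at 168 of the 214 positions. The adjusted p alone was not selective, since 1335 positions lay above and 3383 below their flank at an adjusted p under 0.05 by the same test, and the fold threshold sets the count. The median position lay below its flank mean, at a log2 fold of -0.67. Factors that centre position against flank, with the offset for the number of flank positions kept, moved this median to -0.052 (TMM) or -0.059 (median of ratios), put 2134 positions above and 2214 below with TMM, or 2133 above and 2235 below with the median of ratios, and called 414 or 412 positions enriched, among them all 214. No unoxidised library was analysed here, so the flank is the only background, and an enriched position is not shown to be methylated by this comparison.

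**Figure D1:**
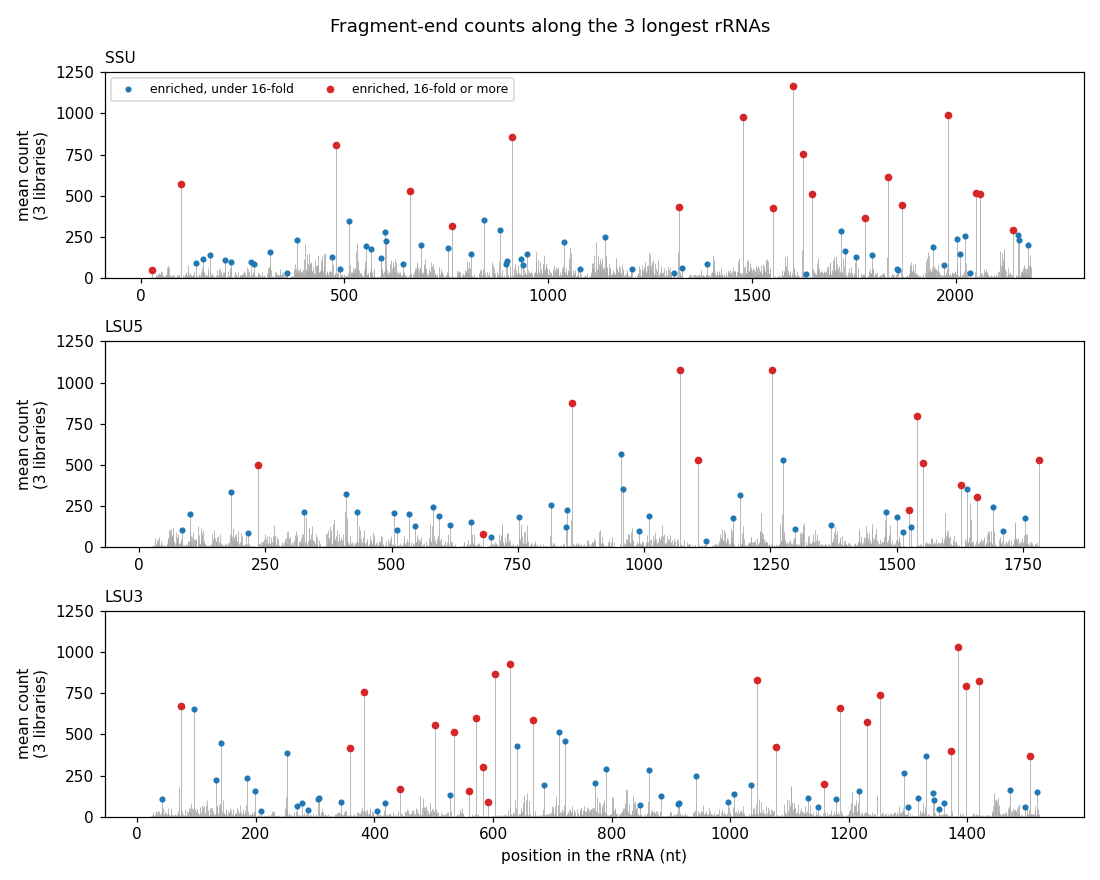
Mean count over 3 libraries (vertical axis) at each position (horizontal axis, nt) of SSU, LSU5 and LSU3, drawn as grey lines. Dots mark enriched positions, red where the estimated fold over the flank was 16 or more (19 positions in SSU, 12 in LSU5 and 24 in LSU3) and blue below that; the highest, SSU position 1600, has a mean count of 1168.

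In SSU, 71 positions were enriched, 26 of them at least 8-fold and 19 at least 16-fold. With the flank of 6 positions on each side, the largest fold was at position 1551, with 426 ± 41.6 counts (SD, n = 3) and 177 ± 54.1-fold over the flank. With 10 positions on each side its log2 fold dropped from 7.35 to 5.69, below that of positions 2049 (6.23), 1600 (5.88) and 98 (5.85). With the flank of 6 positions, position 98 followed, with 574 ± 19.1 counts and 83.3 ± 14.8-fold. With a flank on the 5' side only its log2 fold was 5.75, below positions 1600 (6.51), 2060 (6.06) and 2049 (5.85). Position 2049 reached 64.3 ± 22.0-fold, position 1867 reached 53.5 ± 2.90-fold and position 2060 reached 44.8 ± 11.97-fold. Position 1600 had the highest count of the whole data set, 1168 ± 109, and 53.5 ± 5.17-fold. Positions 1834 and 912, named for their deposited score, were enriched 42.9 ± 5.04-fold and 31.1 ± 6.25-fold. With 3 flank positions on each side their log2 folds were 6.86 and 6.09 in place of 5.41 and 4.94, and position 1834 then lay above positions 98 (6.09) and 2049 (5.66). Between positions 1479 and 1648, 5 positions exceeded the flank by 16-fold or more, namely 1479, 1551, 1600, 1624 and 1648, of which 1479, 1624 and 1648 were chosen after their values were seen.

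In LSU5, 50 positions were enriched, 19 of them at least 8-fold and 12 at least 16-fold. With the flank of 6 positions, position 1253 was highest, with 1080 ± 35.2 counts and 93.6 ± 13.4-fold over the flank. Position 1541 reached 86.4 ± 18.2-fold, and it exceeded position 1253 with 10 flank positions on each side (log2 fold 6.52 against 6.43), with a flank on the 5' side only (6.83 against 6.47, where positions 235 and 1107 also did, with 6.69 and 6.68) and without library 1 (6.56 against 6.51). Position 1107 reached 78.1 ± 14.9-fold. Position 1071 had a similar count to position 1253, 1074 ± 72.2, over a denser background and reached 58.5 ± 2.80-fold. Positions 1627 and 235 reached 61.0 ± 14.3-fold and 56.4 ± 10.5-fold. With 10 flank positions on each side the fold of position 1627 was 1.75 times lower.

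LSU3 held 71 enriched positions, 43 of them at least 8-fold and 24 at least 16-fold. It also gave 11 of the 25 named positions with the largest fold. With the flank of 6 positions, position 1384 had the largest fold of all, with 1030 ± 52.0 counts against a flank mean of 5.81 and 200.1 ± 79.3-fold. The fold ranged from 112 to 266 between libraries while the count ran from 970 to 1063. With 10 positions on each side LSU3 position 604 was higher (log2 fold 7.44 against 7.03), with 3 positions SSU position 1551 and LSU3 positions 534 and 604 were (8.17, 8.15 and 7.37 against 7.29), and with a flank on the 5' side only SSU position 1551 was (8.69 against 8.17). Around position 1384, positions 1397, 1419 and 1372 reached 99.8 ± 14.2-fold, 82.5 ± 12.6-fold and 51.6 ± 19.3-fold. A second set lay at positions 534, 560, 572, 583, 604 and 628. There, position 604 reached 145 ± 19.6-fold with 867 ± 30.7 counts, position 583 reached 131 ± 58.6-fold with 303 ± 75.0 counts, and position 572 reached 109 ± 18.4-fold. Positions 534, 560 and 628 reached 70.7 ± 7.82-fold, 64.2 ± 14.1-fold and 57.4 ± 16.8-fold. With a flank on the 5' side only, the log2 fold of position 560 was 8.04 in place of 5.93, above position 604 (7.58). With 10 flank positions on each side the fold was 3.06 times lower at position 583, and the log2 fold of position 534 dropped from 6.13 to 4.93. With 3 it was 4.05 times higher at position 534, and the log2 fold of position 572 was 6.06 in place of 6.73. The median background in this stretch was low, at 15.5 counts per position over the 3 libraries against 48 elsewhere in LSU3. Position 359 reached 54.9 ± 13.8-fold, and positions 1253 and 667, named for their deposited score, 39.6 ± 8.78-fold and 34.3 ± 1.69-fold. The fold of position 359 was 1.61 times lower with 10 flank positions on each side, and those of positions 1253 and 667 were 1.83 and 1.55 times higher with 3.

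**Figure D2:**
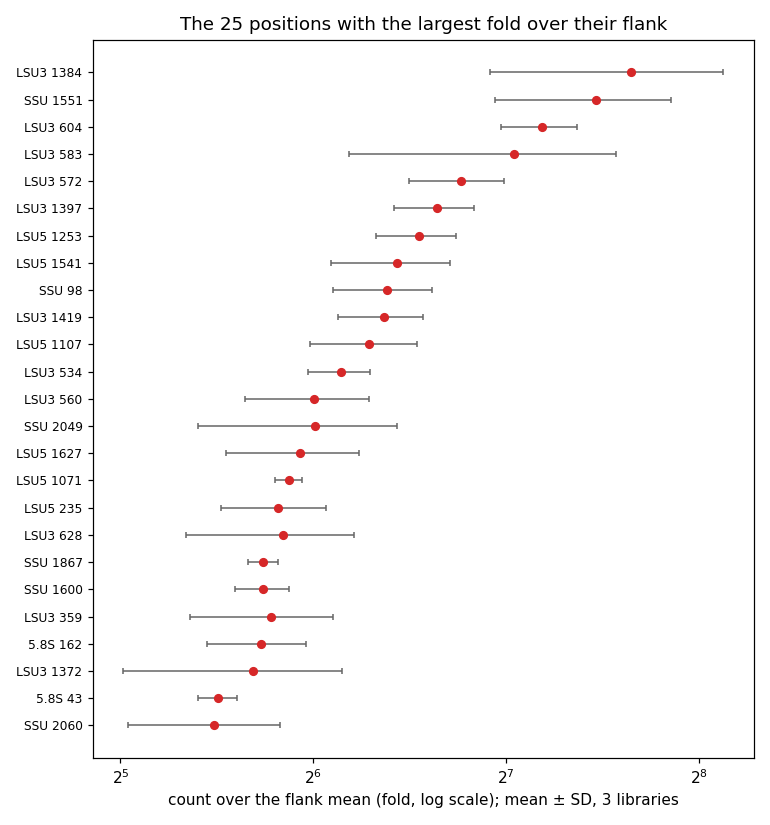
Count over the flank mean (fold, log2-spaced axis) at the 25 named positions with the largest estimated fold; points are means and bars the SD over 3 libraries, with a flank of 6 positions on each side. The means run from 44.8-fold at SSU position 2060 to 200.1-fold at LSU3 position 1384, and many bars overlap.

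For the 25 positions with the largest fold, the largest adjusted p was 1.11e-17 (edgeR's quasi-likelihood test). They were chosen for their fold, so this p is no separate support for them. The flank enters the test as a sum, so the p does not measure the spread between background positions. Over these 25 the median coefficient of variation of the fold between libraries was 18.5%.

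The 5.8S rRNA held 7 enriched positions. Position 162 reached 52.9 ± 9.32-fold with 618 ± 72.3 counts, and position 43 reached 45.5 ± 3.19-fold with 805 ± 47.1 counts. With 10 flank positions on each side the fold of position 162 was 3.24 times lower, at a log2 fold of 4.01, below positions 43 (5.09) and 75 (4.45). With a flank on the 5' side only, position 43 had a log2 fold of 7.72 in place of 5.50, above position 162 (5.96). Positions 75, 124 and 170, chosen after their values were seen, had 21.9 ± 3.67-fold, 10.7 ± 1.09-fold and 8.85 ± 0.171-fold. The other 2, positions 26 and 33, rested on 1 to 7 counts per library, and their fold fell below 4 in at least 1 library. They were not called when at least 100 counts were required in position plus flank, which left 212 of the 214 positions.

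The 4 SR sequences (SR1, SR2, SR4 and SR6) held 15 enriched positions, none of them 16-fold over the flank of 6 positions on each side. The most enriched were SR6 position 72 with 592 ± 49.8 counts and 14.7 ± 2.35-fold, SR1 position 215 with 520 ± 31.4 counts and 14.7 ± 2.34-fold, and SR2 position 102 with 302 ± 40.5 counts and 12.3 ± 3.90-fold. Each of these 3 passed 16-fold with the flank median and limma (log2 folds of 4.11, 4.84 and 4.04 in the same order) and with factors between position and flank (4.48, 4.47 and 4.17 with TMM and the offset kept). The log2 fold of SR1 position 215 was also 4.40 with 10 positions on each side and 3.19 with 3, then below SR2 position 102 (3.36). SR4 position 24 reached only 4.94 ± 0.897-fold with 32 ± 2 counts and was not called with a flank of 3 positions (log2 fold 1.98). The score recomputed with the authors' formula was 11.002 ± 1.32 at SR6 position 72, 8.41 ± 0.843 at SR1 position 215, 6.24 ± 1.67 at SR2 position 102 and 2.49 ± 0.482 at SR4 position 24. SR6 position 72 and SR1 position 215 each lay 1 position before the last listed one. Enriched positions also stood at the last listed position of SR2 (183) and 1 position before the last in 5.8S (170) and LSU5 (1781). These were chosen after their values were seen, and LSU5 position 1781 had 36.2 ± 0.699-fold.

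**Figure D3:**
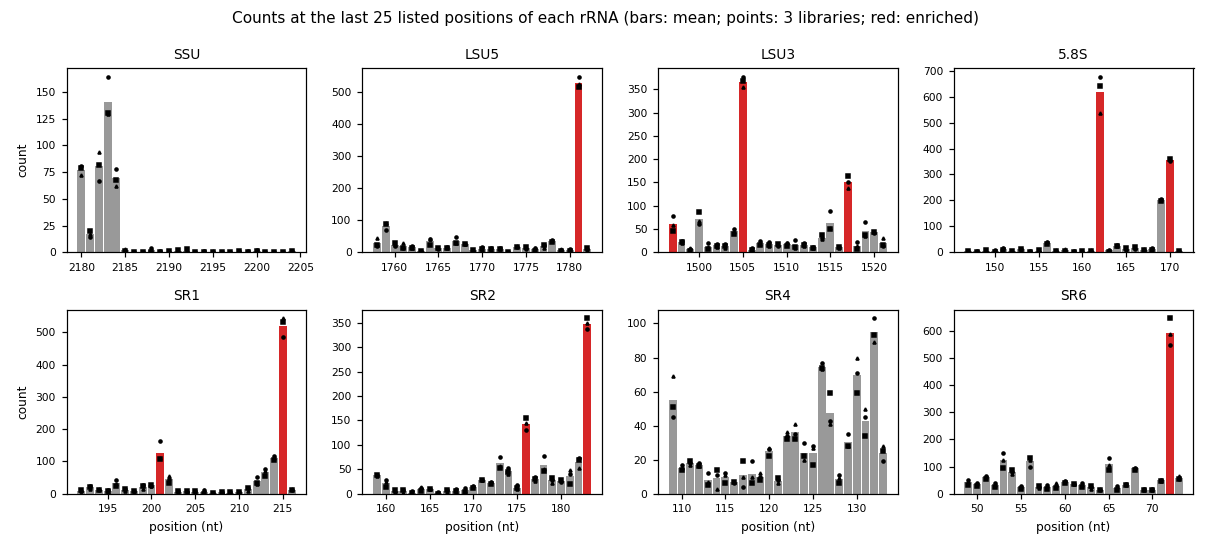
Counts (vertical axis) at the last 25 listed positions (horizontal axis, nt) of the 8 rRNAs; bars are means over 3 libraries, points the single libraries, and red bars the enriched positions. An enriched position stands at or 1 before the last listed position in 5 rRNAs: LSU5, 5.8S, SR1, SR2 and SR6.

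Among the 8 rRNAs, the density of enriched positions differed from the rest past the threshold in LSU3 alone, and this depended on the setting. The density was 4.73 per 100 tested positions in LSU3, 3.26 in SSU, 2.84 in LSU5 and 4.61 in 5.8S, and between 1.75 and 5.56 in the SR sequences, where it rests on 2 to 5 positions each. Against all other sequences together, LSU3 had an odds ratio of 1.56 (two-sided Fisher's exact test, adjusted p = 0.0282 over 8 sequences). This test takes positions as independent, which neighbouring positions with shared flank counts are not. No other sequence passed, and the next lowest adjusted p was 0.309, for LSU5. The LSU3 difference was not past the threshold in 9 of the alternative settings. With a flank of 10 positions on each side the odds ratio was 1.43 (Fisher's exact test, adjusted p = 0.201), and at a fold threshold of 2 it was 0.879 (adjusted p = 0.633, exact test), on the other side of 1. At a threshold of 8 it was 2.40 (adjusted p = 0.000242, exact test).

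The authors' deposited score, which sets each count against its immediate neighbours, put 6 of the named positions with the largest fold among its own 10 highest. In the authors' deposited table the highest scores were 309 at LSU3 position 1384, 202 at LSU3 position 534, 183 at SSU position 1834, 177 at SSU position 1551 and 157 at LSU3 position 583. Scores of 135, 134 and 116 followed at LSU3 positions 604, 1253 and 667, and of 104 and 101 at SSU positions 98 and 912, against a median of 0.808 over 5577 positions in the authors' deposited table. The SD over libraries, obtained by recomputing the score, was 196 for LSU3 position 1384 and 49.2 for LSU3 position 534, so the order of these 2 lies within the spread between libraries. All 10 positions were also enriched over the wider flank. Of the 50 highest-scored positions 48 were enriched, and of the 100 highest 89. Of the 199 highest, as many as there were enriched positions in the 4 scored sequences, 135 were enriched, where 7.10 would be shared by unrelated lists of this size. Both measures come from the same counts. Across positions, Spearman's rho between the score and the log2 fold was 0.72. At 8 enriched positions the deposited score was under 2. Some of these were next to each other, such as LSU3 positions 912 and 913 and SSU positions 1856 and 1857, chosen after their values were seen; their scores ran from 1.63 to 1.94 in the authors' deposited table.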

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

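The number of enriched positions stayed within 1.5 times the reported 214 with DESeq2 (214), without the filter on low counts, with the other flank sizes (204 to 233) and in the further settings not listed next. It was 393 with TMM factors between position and flank and 411 with median-of-ratios factors, where the offset for the number of flank positions was dropped too, 414 and 412 with these factors and the offset kept, 365 with the flank median and limma, 323 with a flank on the 5' side only, 686 at a fold of 2 or more and 99 at a fold of 8 or more. The fold thresholds act by construction; for limma and the 5' flank the cause was not tested. The share of counts at enriched positions, reported as 28.1%, was 35.8%, 36.5%, 36.5%, 36.5%, 34.7%, 31.2%, 45.5% and 21.01% in these 8 settings in the same order, 30.3% with enriched positions left out of the flanks and 25.3% with the test against a fold of 4. The number of rRNAs with a density different from the rest, reported as 1, was 0 with TMM and with median-of-ratios factors (offset dropped or kept), with limma, with 10 flank positions on each side, with the nearest positions left out, with the 5' flank and at a fold of 2; the cause was not tested. Leaving out 1 library gave 209 to 219 enriched positions, a share of 27.2% to 29.2%, 1 differing rRNA in each case and 132 to 135 positions shared with the highest scores; 189 of the 214 positions were called whichever library was left out. Without the library block (no pairing of position and flank within a library) 214 were called; no groups were compared, so no other pairing applies. Taking the 50 or 100 highest scores gave 48 and 89 shared positions, by the smaller lists. Pearson's r for the pairs 1 and 2, 1 and 3, and 2 and 3 was 0.97, 0.96 and 0.97 on the square-root scale, 0.93, 0.93 and 0.93 without the filter, and 0.90, 0.89 and 0.91 without the enriched positions, an alternative chosen after seeing the data, as were the test against a fold of 4, the 5' flank, the factors with the offset kept and the flanks without enriched positions. Of the 33 named positions, 32 were enriched in each of the settings that tested them. The exception, SR4 position 24, was not called with 3 flank positions, at a fold of 8 and against a fold of 4. With 12 positions at each sequence end left out, only 29 of the 33 were tested. Since 25 were picked for the largest fold, the calls of the named positions could hardly change in most settings. Their folds and order depended on the flank more than their calls did: with 3 or 10 positions on each side, 13 of the 33 moved by over 1.5 times and by up to 4.05 times, 11 did with the 5' flank, by up to 4.66 times, and 7 with limma. All 33 did with median-of-ratios factors, by up to 2.61 times, or 1.53 with the offset kept. All 33 also did with TMM factors and the offset kept, by up to 1.53. With the offset kept this was a nearly uniform shift, between 1.5 and 1.53 times at each of the 33. TMM factors with the offset dropped moved 3 past 1.5 times, by up to 2.54, and the others by just under 1.5. Each printed fold thus depends on the centring.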

Other observations

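All tests in this part were chosen after the pattern had been seen. A wide flank hides enriched neighbours from each other. Among the 214 enriched positions, 12 followed another within 6 positions, where random placement gave 41.7 on average (95% of 1000 placements between 32 and 52). When enriched positions were left out of the flanks, 267 were called, all 214 among them. The positions gained lie within 6 positions of another enriched one by construction, so their number does not show how often methylated nucleotides neighbour each other. They include SSU position 1622, with 176, 186 and 156 counts beside the higher SSU position 1624, LSU3 position 1248, with 108, 124 and 165 counts, and 5.8S position 169, with 205, 201 and 197 counts. Their log2 folds in this setting were 4.68, 4.28 and 3.996. 5.8S position 169 adjoins the enriched position 170, 1 before the last listed one, which is treated with the sequence ends below. SR1 position 214, also gained, adjoins SR1 position 215 likewise. Neither is shown to be a site separate from the sequence end. SSU position 1622 had a score of 67.2 in the authors' deposited table, the highest of any position not among the 214.

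Counts at some enriched positions differed between the libraries. At 63 of the 214 positions the counts differed between libraries by more than counting noise (chi-square test, Benjamini-Hochberg over 214; duplicate reads, if not removed, add to this), and at 43 of these 63 library 1 was lowest relative to its total. LSU3 position 711 had 152, 273 and 290 counts per 100000 in libraries 1, 2 and 3, and LSU3 position 502 had 186, 257 and 322. Depth matters here. A position not called enriched, with a total count within 10%, was found for 122 of the 214 enriched positions. In these pairs 30 enriched and 31 other positions differed at an unadjusted p under 0.05 (chi-square test, with exact McNemar p = 1 for the pairs). The matched enriched positions thus did not differ more often than others. Their median total was 335 counts, while LSU3 position 711 had 349, 581 and 621 counts in libraries 1, 2 and 3. The comparison does not speak for enriched positions without a match. The median ratio of the highest to the lowest library over all 214 positions was 1.21. Each strain designation has 1 library, so these values compare libraries.

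Enriched positions stood at the end of several rRNAs. In 5 of the 8 sequences (LSU5, 5.8S, SR1, SR2 and SR6) 1 of the last 2 listed positions was enriched, where random placement gave 0.562 on average (permutation test with 100000 draws, p = 9e-05). The last 2 positions of SSU had too few counts to be tested. A shortened flank was argued against as the cause: when every position of every rRNA was given a flank on the 5' side only, random placement gave 0.826 such sequences on average, and 5 were again seen at the ends (permutation test with 100000 draws, p = 0.00039). In LSU5, 5.8S, SR1 and SR6 the last listed position itself had mean counts of only 9.33, 6, 11.7 and 57.3. The enriched position before it had 528, 357, 520 and 592. A candidate explanation is that the natural 3' ends of the rRNAs entered the libraries. Without methylation this would need ends that escaped oxidation, which was not measured. Where the natural ends lie in the numbering used is not given. Methylation of the last nucleotides is not excluded, and no biological explanation was tested.

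The strongest positions were crowded in 1 stretch of LSU3. Between positions 534 and 633, 7 positions were enriched 16-fold or more, the 6 named ones and position 591 with 42.6 ± 6.76-fold. Random placement of the same numbers gave as many in some window of 100 positions with a frequency of 0.046, which argues weakly against chance. The background there was low, and a low background could raise the fold: of the 24 LSU3 positions with the highest counts, regardless of flank, 4 lay in the stretch against 1.60 expected (exact hypergeometric p = 0.0702). The stretch was picked for its crowding in these same counts, so this test cannot tell whether the crowding rests on the background. That stays open, as does a local excess of methylation, which was not tested.

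Counts around the strongest positions were low, most of all just before them. At the position before 58 such sites the median was 0.322 times the median of the rRNA, and at the position after it was 0.726 times. The low level was not confined to the nearest positions. It was 0.527 times at 16 positions before the site and 0.491 times at 8 positions after it. Choosing sites for a low flank was argued against as the whole cause, because among as many positions ranked by count alone the flank median was still 0.525 times that of the rRNA (95% bootstrap interval 0.451 to 0.901, n = 57 positions). Removal of 3' nucleotides step by step until a methylated ribose stops it could deplete the 3' side, but the median log2 ratio of 3' to 5' counts over 4 positions on each side was 0.325, higher on the 3' side at 36 of 57 sites (two-sided sign-flip permutation p = 0.0631). The side with fewer counts thus lay opposite to this explanation without passing the threshold, and the spread between sites keeps it open, as does the unknown numbering of the fragment end.

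The deposited score skipped positions without a row. Taking such neighbours as 0 changed 27 of the 5577 scores. SSU position 29, with 54, 38 and 54 counts, had 21.3 in the authors' deposited table and 42.7 with neighbours at 0. LSU5 positions 678 and 421 had 2.01 and 2.00 in the authors' deposited table and 11.7 and 9.98 with neighbours at 0; neither was enriched over the wider flank.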
